A study of Rattus norvegicus with 22 samples.

How the data were processed

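Total RNA from the right lungs of male Wistar rats was labelled with Cy3 and hybridised to Agilent whole rat genome oligonucleotide arrays, per the labels' protocols. Rats had received a single intratracheal instillation of C60 fullerene particles, a carbon nanomaterial, suspended in water with Tween-80, or that vehicle alone. The 22 samples form a low-dose set, with vehicle, 0.1 mg and 0.2 mg C60 per rat at 1 week and at 1, 3 and 6 months (12 samples), and a high-dose set, with vehicle and 1.0 mg at 3, 7, 30, 90 and 180 days (10 samples). Each sample is 1 column of values that stands for 2 to 6 rats, per the labels. Whether RNA was pooled or arrays of single rats were averaged is not given in the sources used here, and the series text gives a narrower range of rats per group than the sample labels do. The spread between rats of a group could therefore not be read from the values.

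The deposited table holds values on a log scale, taken here as log2 because both signs occur and no base is stated. It has 41012 probes and 0 missing values. The authors' scanner software, scaling between arrays, baseline and way of combining rats are not given in the sources used here. The values themselves make it likely that each probe was set relative to the vehicle rats of its own set and time point, and they are read so here. The 9 vehicle columns had medians from -0.05 to 0.01 and SDs from 0.10 to 0.17, against SDs from 0.29 to 0.71 in the 13 treated columns. Columns of the low-dose set carry 4 decimals and those of the high-dose set 3. A probe's signal level is therefore lost. If the base were not 2, every fold given would change while every sign, rank and test would stay.

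For each treated sample the vehicle sample of the same set and time point was subtracted probe by probe. With 1 sample per dose and time point no test is possible within a time point, so the spread in every test comes from variation between time points. The 12 low-dose samples were fitted together. The tests of 0.1 mg, of 0.2 mg and of 0.2 mg against 0.1 mg therefore share 1 estimate of the spread. The 3 dose comparisons, 0.2 mg against 0.1 mg, the 1.0 mg response minus the 0.2 mg response at the 4 time points of both sets (16 samples), and the slope of the 1.0 mg response on log10 of the day were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Time point was a block in each, because vehicle and treated samples are matched by it in the labels. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 41012 probes. A difference of 1 on the log2 scale is called 2-fold. The number of arrays limits the precision.

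The comparisons, tests, naming rule and most alternatives were fixed before the data were examined. Departures followed from what the table holds. The fixed rule would have subtracted each array's 75th percentile, since these percentiles differed by more than the limit set. That rule was written for signal levels. In a table of differences from vehicle the 75th percentile measures spread, so the values were used as deposited, and the subtraction is reported as an alternative. This choice was made after the values were seen. A trend in vehicle rats over time and a comparison of the vehicle rats of both sets were also planned. Both are treated as void, as the vehicle columns appear to be centred on themselves. The 2-fold count between the vehicle samples of both sets, planned as the background, is treated as void too. Filters and floors on weak signals had no level to act on, so no probe was left out.

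None of the 41012 probe IDs occurred in the gene table at hand (0 matches), and the files do not pair probes with genes. The 36 gene lists fixed beforehand and the rules for naming genes could not be used. At most 2 probes in each direction are named per comparison, by ID. They are those with the highest and lowest mean difference over time points among probes on 1 side of vehicle at every time point. Any other named probe is said to have been chosen after its values were seen.

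Groups of probes were compared with 10000 random lists of the same size, matched on the root mean square difference over the other samples in 20 bins, and the 2.5th and 97.5th percentiles of their medians are given as the range. To check that a group held beyond the samples it was chosen in, the 100 probes with the highest mean at all time points but 1 were read at the time point left out. The correlation of the low doses, which share vehicle samples, was set beside that of simulated unchanged groups that share a simulated vehicle group. The simulation used the labelled numbers of rats. Its spread per rat was inferred from the width of the vehicle columns, which is an assumption. Only 1 vehicle column exists per time point, so vehicles could not be divided. Counts of probes on 1 side of vehicle at every time point, the reading at a time point left out and the description of a band of probes that shifted together were chosen after the values were seen.

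Alternatives were centring each array on its median, subtracting the 75th percentile, quantile normalization, weights by number of rats, moderation with a trend, all 22 samples in 1 fit, a fit without the time-point block, and leaving out each time point. Leaving out the band was added after the values were seen. Quantile normalization stretches the narrow vehicle columns to the width of the treated ones. The fit was tested on simulated data with the real design and each probe's fitted spread. For 1.0 mg, 70.1% of 67 probes with a simulated difference of 1 and 92.5% of 67 with a difference of 2 were called, and 5.19% of unchanged probes had p under 0.05. For 0.2 mg these shares were 58.2%, 100% and 4.96%. For 0.1 mg they were 59.7%, 100% and 5.00%. In each simulation 67, 67 and 66 probes with differences of 1, 2 and 3 were changed together, with spread independent between probes. The shares depend on these numbers of changed probes, since the adjusted p does. They hold for the spreads simulated and do not extend to probes whose difference varied widely between time points. Real probes also shifted together in bands, described below, so the shares do not give the power of the real tests. For 1.0 mg, 66 of 66 probes with a simulated difference of 3 were called. A_44_P739541, with a real mean of 3.80 ± 1.23 (SD), had a limma adjusted p of 0.217. Figures were drawn with matplotlib 3.10.9.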

Results

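Gene expression was measured in rat lung after a single instillation of C60 fullerene into the trachea, to follow how the tissue responded to a particle deposit over time and dose. Vehicle rats and rats given 1.0 mg were sampled at 3, 7, 30, 90 and 180 days, and vehicle rats and rats given 0.1 or 0.2 mg at 1 week and at 1, 3 and 6 months. Each of the 22 samples had 1 value for each of 41012 probes, read here as relative to vehicle rats of the same set and time point. A sample stood for 4 rats at every point of the high-dose set and for 2 to 6 rats in the low-dose set. There were no replicate samples within a dose and time point, so errors below describe variation between time points. The files do not pair probes with genes, so probes are given by ID and no gene can be named.

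After 1.0 mg C60, a small group of probes was far above vehicle from the first to the last time point. By at least 2-fold at all 5 time points, 19 probes were higher and 0 were lower. The median difference of the 19 probes was 2.84 on the log2 scale at 3 days, 3.46 at 7 days, 2.55 at 30 days, 1.70 at 90 days and 1.71 at 180 days. In a wider group, 79 probes were above vehicle at every time point with a mean of at least 2-fold, and 1 probe was below in the same sense. These counts depended on the scaling of arrays. Subtracting the 75th percentile left 43 above and 4 below, and quantile normalization 35 and 8, while 167 were above when 6 months was left out. The count at least 2-fold higher at all 5 time points was 18 with each array centred on its median, 15 after subtracting the 75th percentile and 10 after quantile normalization. The median of the 79 probes was 1.49, 1.75, 1.43, 1.05 and 0.86 in time order. These probes were chosen on the same samples, so their heights in the 1.0 mg arm are not a test.

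The probe with the highest mean, A_44_P739541, was 13.9-fold above vehicle, with a log2 difference of 3.80 ± 1.23 (SD, n = 5 time points). Its difference was 5.69 at 3 days and 3.51 at 180 days. The next, A_42_P662543, was 10.7-fold above vehicle (3.41 ± 0.73, SD, n = 5) and peaked at 30 days with 4.18. Below vehicle at every time point, A_44_P829197 had a mean of -1.04 ± 0.34 (SD, n = 5), and A_44_P281833 was lowest at 90 days with -1.89. None of these 4 probes passed the test, with limma adjusted p-values of 0.217, 0.195, 0.241 and 0.414. Over the alternatives the adjusted p ran from 0.000205 to 0.549 for A_44_P739541 and from 0.000114 to 0.549 for A_42_P662543. For A_44_P829197 the limma adjusted p ran from 0.0150, in the fit of all 22 samples, to 0.819. For A_44_P281833 the limma adjusted p ran from 0.102 to 0.741.

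Probes chosen as the highest stayed above vehicle at time points that had no part in the choice. When the 100 highest probes were chosen on 4 time points, their median at the point left out was 0.85 at 3 days, 1.00 at 7 days, 0.93 at 30 days, 0.69 at 90 days and 0.45 at 180 days. Each value lay above the range of matched random lists, whose upper bounds were 0.09, 0.08, 0.16, 0.12 and -0.01. After quantile normalization the lowest of the medians was 0.208. Of the 100 probes, 71 to 93 were above vehicle at the point left out. The 100 lowest probes did not hold in the same way. Their medians were -0.27 at 3 days, -0.09 at 7 days and -0.14 at 180 days, but 0.23 at 30 days and 0.11 at 90 days. Those at 3, 7 and 180 days lay below the random lists (lower bounds -0.05, -0.05 and -0.09). The median at 30 days lay above its lists (upper bound 0.155) and that at 90 days within them.

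Across all probes, limma called 0 higher and 0 lower after 1.0 mg, and 4902 probes (3315 higher, 1587 lower) had an unadjusted p under 0.05, against 2050.6 expected by chance. Of the 3315 higher probes, 1164 (35.1%) lay in a band of probes that shifted together, described below. The 4902 became 2480 when 3 days was left out and 13532 when the 75th percentile was subtracted, the lowest and highest of the alternatives. The count of calls depended on how the spread was estimated. A fit of all 22 samples called 49 higher and 1 lower, and a fit without time point as a block called 66 higher and 8 lower.

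**Figure D1:**
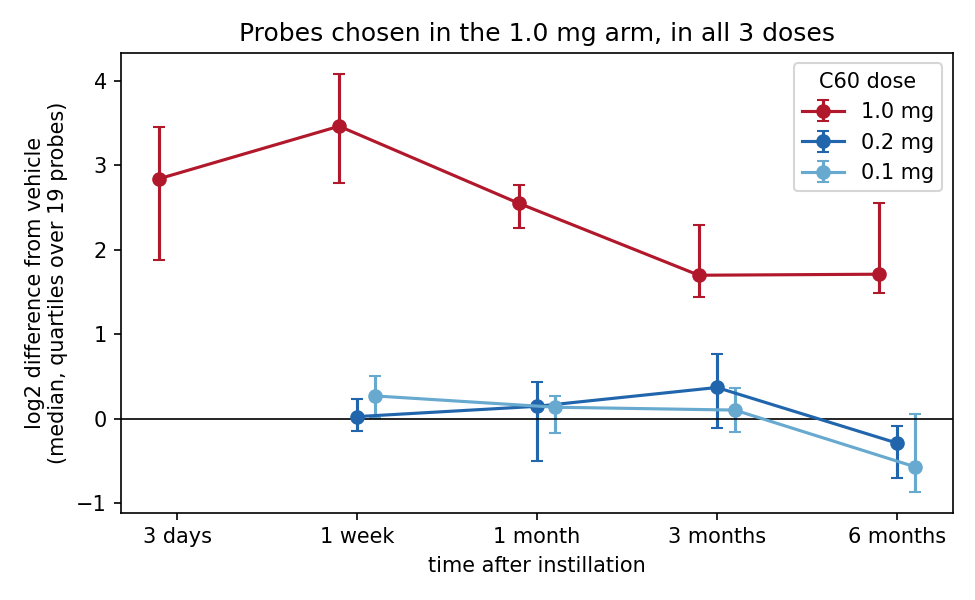
Median log2 difference from vehicle (points, with quartiles over probes as bars) of the 19 probes that were at least 2-fold higher at all 5 time points after 1.0 mg, against time after instillation, for each dose. The 1.0 mg medians run from 1.70 to 3.46, and all medians at 0.1 and 0.2 mg lie between -0.57 and 0.37.

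In the low-dose set these probes were not lastingly above vehicle. The mean of the medians of the 19 probes over 4 time points was 0.07 ± 0.27 after 0.2 mg and -0.01 ± 0.38 after 0.1 mg (SD, n = 4). With 4 time points no exact sign-flip test can reach 0.05, so none is given. At 6 months their median after 0.1 mg was -0.57, below the range of random lists (-0.29 to 0.16), and after 0.2 mg it was -0.28, within it (-0.31 to 0.16). The wider group of 79 had medians at 6 months of -0.29 after 0.1 mg and -0.25 after 0.2 mg, both below the random lists (from -0.15 and -0.17). Its median also lay below them at 3 months after 0.2 mg, with 0.08 (0.16 to 0.68), and marginally above them at 1 week after 0.1 mg, with 0.27 (-0.02 to 0.27). Dose and set cannot be told apart here, because the 1.0 mg rats had their own vehicle rats and sampling days.

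The response to 1.0 mg was compared directly with that to 0.2 mg at the 4 time points of both sets. One probe, A_44_P555271, passed this test (limma, adjusted p = 0.0474). Its 1.0 mg difference exceeded its 0.2 mg difference by 3.38 ± 0.35 (SE). After 1.0 mg it was 9.82-fold above vehicle, with differences of 3.82, 4.29, 2.60, 2.91 and 2.85 in time order, and after 0.2 mg its mean was -0.22 ± 0.37 (SD, n = 4). It was among those at least 2-fold higher at all 5 time points, and it was chosen for naming after its values were seen, as the only probe called. The call was lost when 1 week, 1 month or 3 months was left out (adjusted p = 0.0721, 0.579 and 0.267), while the difference stayed at 3.08, 3.39 and 3.47. When 6 months was left out it was 3.58, with an adjusted p of 0.301, and 1 other probe was called. Over 11 alternatives the adjusted p of A_44_P555271 ran from 0.00582 to 0.579. Subtracting the 75th percentile raised the count to 12, and quantile normalization lowered it to 0.

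After 0.2 mg C60, other probes stood above vehicle. The probe with the highest mean, A_44_P194939, was 4.52-fold above vehicle (2.18 ± 0.63, SD, n = 4), with differences of 1.52, 2.97, 2.36 and 1.85 at 1 week and 1, 3 and 6 months. After 0.1 mg the same probe was at 1.49, 0.73, 0.50 and 1.25, and after 1.0 mg its mean was -0.15 ± 0.17 (SD, n = 5). A_44_P505440 also stood above vehicle at both low doses, with means of 2.10 ± 0.97 after 0.2 mg, 0.95 ± 0.47 after 0.1 mg and -0.18 ± 0.28 after 1.0 mg, and with 0.84 at 3 months after 0.2 mg. Both low doses are measured against the same vehicle samples, and simulated unchanged groups correlated at 0.288 to 0.597 between them, so these probes at 0.1 mg are no independent test. Below vehicle at every time point after 0.2 mg, A_44_P852414 had a mean of -2.01 ± 2.68, which rested on -6.03 at 6 months, and A_44_P251031 a mean of -1.80 ± 0.84 (SD, n = 4).

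Probes chosen as the 100 highest on 3 time points after 0.2 mg also stayed above the random lists at the point left out, with medians of 0.42, 0.55, 0.96 and 0.43 against upper bounds of 0.27, 0.42, 0.89 and 0.17. The 100 lowest lay below the lists at all 4 points, with -0.28, -0.31, 0.24 and -0.40 against lower bounds of -0.05, 0.00, 0.72 and -0.05. At 3 months, however, 59 of the 100 were above vehicle, and their median was near that of all probes (0.23). The lists there ran from 0.72 to 0.89, so at that point the choice did not hold below vehicle.

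At 0.2 mg, 182 probes were above vehicle at every time point with a mean of at least 2-fold and 17 below, and by at least 2-fold at all 4 time points 8 were higher and 1 lower. The counts on 1 side of vehicle depended on the scaling, and their balance reversed only after subtracting the 75th percentile. With each array centred on its median 107 were above and 44 below, after subtracting the 75th percentile 21 and 544, and after quantile normalization 61 and 6. Leaving out a time point gave 128 to 451 above and 40 to 55 below. The median of the 182 probes after 0.1 mg was 1.31 at 1 week, 0.35 at 1 month, -0.19 at 3 months and 0.50 at 6 months, measured against the same vehicle samples. Random lists ranged from 0.14 to 0.28, 0.24 to 0.42, -0.12 to -0.06 and 0.09 to 0.19, so the value at 1 month lay within its range and that at 3 months below it. After 1.0 mg their medians lay between -0.12 and 0.18, below the random lists at 3 days and 30 days. Limma called 0 probes at 0.2 mg, with a lowest adjusted p of 0.107, and 6792 probes (4295 higher, 2497 lower) had an unadjusted p under 0.05, with 4182 to 12035 over the alternatives. Weighting samples by rats called 2 higher, A_44_P194939 and A_44_P505440, a fit of all 22 samples called 3 higher, both of these and A_44_P854339, and leaving out 3 months, where the 0.2 mg sample stood for 2 rats, called 1 higher, A_44_P505440. A_44_P854339 was chosen for naming after its values were seen.

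After 0.1 mg C60, no probe passed the test. The spread in this test was estimated from all 12 low-dose samples together, the 0.2 mg samples included. Limma called 0 probes, and 823 had an unadjusted p under 0.05, fewer than the 2050.6 expected by chance. That count depended on the time points and on the scaling: it was 4537 when 3 months was left out, 437 without 1 month, 275 without 1 week and 3970 after quantile normalization. At every time point and with a mean of at least 2-fold, 8 probes were above vehicle and 4 below, against 7 and 8 with each array centred on its median, 2 and 22 after subtracting the 75th percentile and 10 and 6 after quantile normalization. When 3 months was left out, 90 were above. The 100 probes highest on 3 time points had medians at the point left out of 0.37, 0.28, -0.24 and 0.11, above the random lists at 1 week only (upper bound 0.34) and below them at 3 months (lower bound -0.14). The 100 lowest had -0.04, 0.06, -0.02 and 1.12, the last far above its lists (upper bound 0.29). Those at 1 week and 1 month lay below their lists (lower bounds 0.11 and 0.13), and that at 3 months within them. The highest mean was that of A_44_P139500 (1.37 ± 0.92) and the lowest that of A_43_P16181 (-1.60 ± 0.78, SD, n = 4), both with an adjusted p of 1.00. A_43_P16181 had a mean of -1.78 ± 1.11 after 0.2 mg against the same vehicles.

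The low doses were also compared with each other, to ask whether the higher dose gave another response. Limma called 0 probes between 0.2 and 0.1 mg, and 2054 had an unadjusted p under 0.05, against 2050.6 expected by chance. Over the alternatives this count ran from 818 after quantile normalization to 4205 in a fit of all 22 samples, and it was 3253 when 1 week was left out. Over all probes, the differences after 0.1 and 0.2 mg correlated at r = 0.637 at 1 week, 0.551 at 1 month, -0.300 at 3 months and 0.625 at 6 months. Probes are not independent replicates. Simulated unchanged groups with a shared simulated vehicle group and the labelled numbers of rats gave 0.597, 0.444, 0.288 and 0.505. The observed covariance exceeded the simulated one by 0.056, 0.035 and 0.068 at 1 week, 1 month and 6 months. It was 0.161 below it at 3 months, a difference of -0.161. The simulated covariance rests on the spread per rat inferred from the vehicle columns. At 3 months after 0.1 mg that spread predicted an SD of 0.498, against 0.345 observed, so no conclusion is drawn from these covariances. Both doses share the vehicle sample, and with 1 vehicle sample per time point it could not be divided.

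No probe had a slope of the 1.0 mg response over time that passed the test. Limma called 0 probes, 1606 had an unadjusted p under 0.05, and the lowest adjusted p was 0.982. Over the alternatives the count at p under 0.05 ran from 1177 to 3354, the highest when 1 month was left out, with a lowest adjusted p of 0.594 there. A_44_P739541 had a slope of -1.26 per 10-fold increase in days (adjusted p = 0.982).

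At single time points, without a test, the number of probes at least 2-fold from vehicle varied widely. After 1.0 mg, 1191 probes were higher and 193 lower at 3 days, 850 and 345 at 7 days, 3104 and 565 at 30 days, 918 and 216 at 90 days, and 326 and 283 at 180 days. After 0.2 mg, 936 were higher and 781 lower at 1 week, 391 and 282 at 1 month, 4225 and 2014 at 3 months, and 1710 and 710 at 6 months. After 0.1 mg, 1340 were higher and 657 lower at 1 week, 440 and 199 at 1 month, 148 and 492 at 3 months, and 1090 and 331 at 6 months. After quantile normalization the total at 30 days after 1.0 mg was 898, the lowest of the 5 time points, and that at 3 months after 0.2 mg was 1373. That scaling gives every column the same shape by construction, and under it the total at 180 days after 1.0 mg rose from 609 to 1368.

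**Figure D2:**
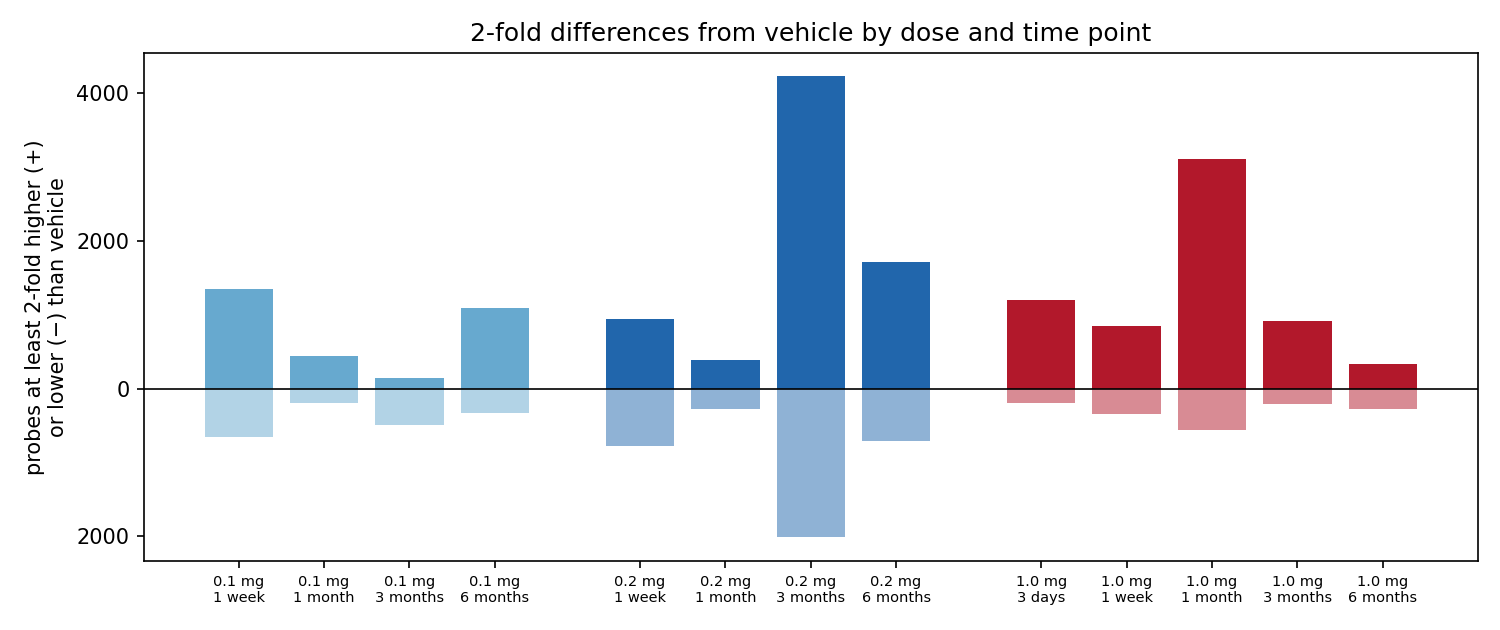
Number of probes at least 2-fold higher (bars above 0) or lower (bars below 0) than the vehicle sample of the same set and time point, for each dose and time point. The highest totals are 6239 probes 3 months after 0.2 mg and 3669 probes 1 month after 1.0 mg.

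The balance of higher and lower probes in these counts depended on the scaling of arrays. The median difference over all probes ranged from -0.10 to 0.23 between treated samples. Centring each array on its median moved the share of higher probes from 67.1% to 43.9% at 1 week and from 68.9% to 43.5% at 1 month after 0.1 mg. After 0.2 mg it moved from 54.5% to 35.1% at 1 week, from 58.1% to 32.1% at 1 month, from 67.7% to 30.3% at 3 months and from 70.7% to 80.7% at 6 months. At 30 days after 1.0 mg it moved from 84.6% to 70.0%. Over all 13 treated samples the share of higher probes ran from 23.1% to 86.1% as deposited, from 6.72% to 63.6% after subtracting the 75th percentile, and from 33.1% to 58.1% after quantile normalization.

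Many probes had nearly the same difference in each of 2 samples. At 30 days after 1.0 mg, 3516 probes lay between 0.9 and 1.3 on the log2 scale. A second band, between 0.8 and 1 at 3 months after 0.2 mg, held 7369 probes, 18.0% of the array. The bands shared 2426 probes, against 631.8 for independent lists. Of the 3104 probes higher at 30 days, 66.3% lay in the 0.2 mg band. Without that band, 1047 higher and 423 lower probes were left at 30 days after 1.0 mg and 651 higher and 139 lower at 3 days. Of the 79 probes above vehicle at every time point after 1.0 mg, 67 lay outside it, as did 16 of the 19. A_44_P739541 lay inside it, with 0.97 at 3 months after 0.2 mg.

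**Figure D3:**
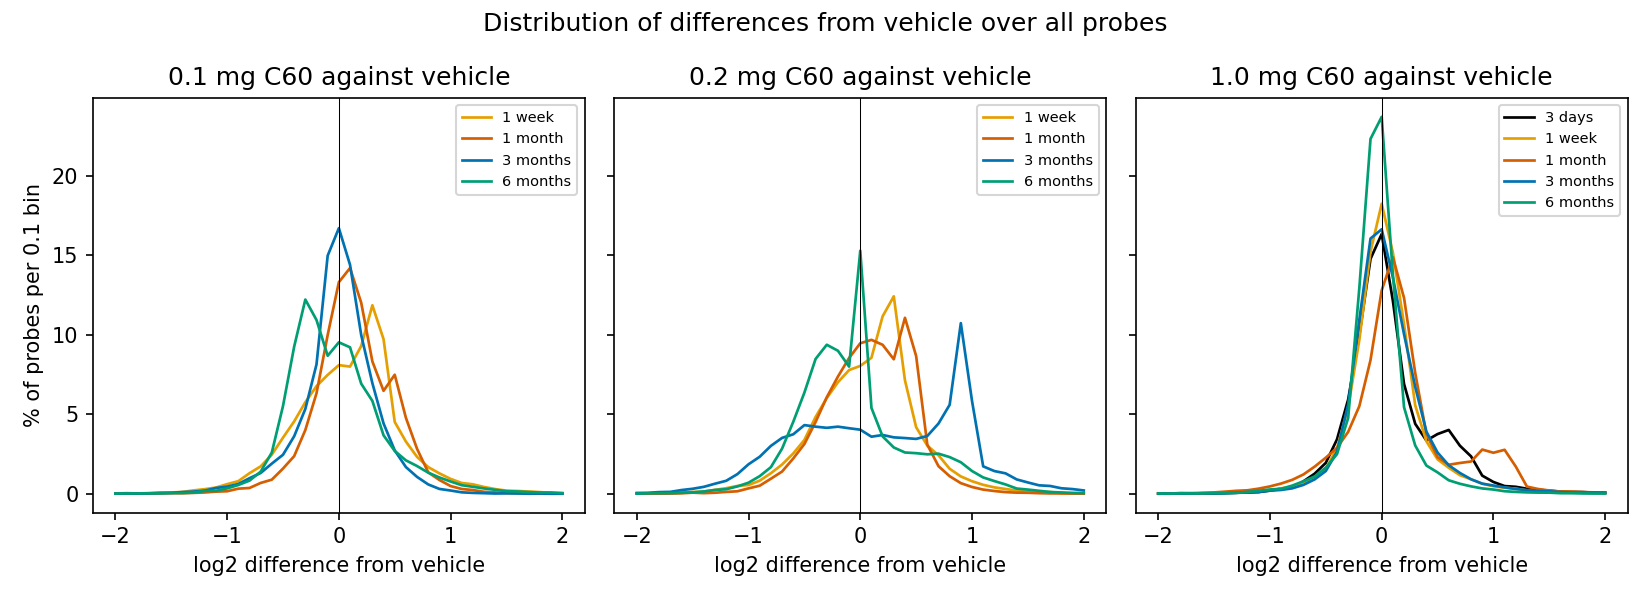
Percent of the 41012 probes in each 0.1-wide interval of the log2 difference from vehicle, drawn from -2 to 2, with 1 line per time point in 1 panel per dose. At 3 months after 0.2 mg a sharp peak lies between 0.8 and 1, at 1 month after 1.0 mg a smaller one between 0.9 and 1.3, and several other lines also have more than 1 peak.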

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

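The tests of explanations for the band and for the 19 probes, exchanges of vehicle and treated included, were chosen only after the result was seen. Of 53 sets of 4 or 5 time points checked for a sample far from the others, 3 had one, against 2.65 expected by chance at 1 in 20.

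The count of probes at least 2-fold from vehicle 1 month after 1.0 mg, 3669, stood far above the other 4 time points. The next was 1384. After quantile normalization it was 898, the lowest of the 5. That scaling gives every column the same shape by construction, so the fall does not test the count. The total at 6 months rose from 609 to 1368 under it. Of the 3104 higher probes 1 month after 1.0 mg, 66.3% lay in a band that formed a peak 3 months after 0.2 mg and held 18.0% of all probes. The probes between 0.9 and 1.3 in this sample are called the 1.0 mg band. It shared 2426 probes with the band 3 months after 0.2 mg, against 631.8 for independent lists, in samples that share no rats. This overlap argues against spread between rats that is independent from probe to probe, but spread shared by many probes stays open. Medians of the 1.0 mg band and of all other probes lay 0.76 apart 3 months after 0.2 mg. A shift of the whole array leaves this gap unchanged by construction, so the gap does not test the count. A shift may account for part of the count, which became 2681 with each array centred on its median, while 1384 became 1348. A response to C60 stays open. The 1.0 mg band had a median of -0.20 in the 3-month vehicle sample of the low-dose set, below the random lists (-0.10 to -0.09). It lay outside the lists in all 9 vehicle samples, but apart from this 1 sample within 0.1 of 0. That margin was chosen after the values were seen. Vehicle columns appear to be centred on themselves, so values near 0 there are likely by construction and decide nothing. Weak probes held at a shared floor are a candidate explanation for the 1.0 mg band, whose interquartile range was below the random lists in 12 of the 12 other treated samples, but for the 0.2 mg band this held in 9 of 12 and the range was wider than the lists in 2 (0.68 at 3 days and 1.04 at 30 days after 1.0 mg), and no signal levels are in the table.

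A_44_P555271 differed between the 1.0 mg and 0.2 mg responses by 3.38 in the test of the difference itself, and it belongs to the 19 probes at least 2-fold higher at every time point after 1.0 mg. Spread between rats that is independent from probe to probe is argued against by probes read at a time point left out of the choice. Their lowest median was 0.45, where random lists reached -0.01, although after quantile normalization the lowest was 0.208. These were the 100 highest probes of each choice, not the 19 probes themselves. The random lists draw probes independently, so spread between groups of rats that many probes share stays open. Chosen in the same way, the 100 lowest after 1.0 mg lay above their lists at 30 days (0.23, upper bound 0.155). A shift of whole arrays is argued against by the 18 of 19 probes that kept at least 2-fold at every time point with each array centred on its median, while 15 were left after subtracting the 75th percentile and 10 after quantile normalization, which also reshapes each array. Exchanging vehicle and treated samples at some time points gives 16 arrangements, too few for a share under 0.05: the real arrangement, 1 of the 16, gave 19 probes and the highest other gave 1, but for probes on 1 side of vehicle with a mean of at least 2-fold the real arrangement, again 1 of 16, gave 80 and the highest other 79. A lasting response to 1.0 mg may account for the 19 probes, as a hypothesis. A difference in the shape of arrays, spread between groups of rats, the set and anything shared by the 1.0 mg rats stay open.

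A_42_P662543 stood at -1.49 at 6 months after 0.2 mg, while its lowest value at the other time points of that dose was 0.39. Against the same vehicle sample it stood at -1.09 at 6 months after 0.1 mg. Its values at the other time points of 0.1 mg ran from 0.08 to 0.62. A_44_P852414 stood at -6.03 at 6 months after 0.2 mg, while its lowest value at the other time points of that dose was -0.81.

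The numbers of called probes were set against other divisions of the same samples, but the real division called 0 probes at each dose. Every division gives at least that many (100 of 100 for 1.0 mg, 35 of 35 for 0.2 mg and 35 of 35 for 0.1 mg), so the comparison decides nothing. The highest counts of the other divisions were 8, 0 and 1.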

How the results depend on the processing

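Counts of probes on 1 side of vehicle at every time point, the median at a time point left out and the fits without the band were chosen only after the result was seen. None of the 13 probes followed through the alternatives changed sign, but the balance of higher and lower probes turned with the scaling, as given below. Of the alternatives, 139 values of main results stayed on their side of the threshold or within 1.5 times the reported count. These 139 include tests that called no probe in the main fit and none in the alternative, so their number does not measure robustness. Of the other values of main results, 61 moved further than that. Another 5 gained calls where the main fit had none, and 5 lost all calls. For those given below the cause was not tested, except where stated.

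A fit of all 22 samples called 50 probes for 1.0 mg, 3 for 0.2 mg and 14 for the difference of the responses, against 0, 0 and 1. With no replicate block, that is without time point as a block, 74 probes were called for 1.0 mg. Of the probes called for 1.0 mg, 27 were shared by both fits. Weighting by rats called 2 for 0.2 mg, and moderation with a trend called 0 for the difference of the responses.

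With each array centred on its median, 3 probes were called for the difference of the responses, against 1. With a mean of at least 2-fold on 1 side at every time point, 2 were lower after 1.0 mg, 107 higher and 44 lower after 0.2 mg, and 8 lower after 0.1 mg, against 1, 182, 17 and 4. By at least 2-fold at every time point, 0 were lower after 0.2 mg, against 1.

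Subtracting the 75th percentile called 12 for the difference of the responses. It gave 43 higher and 4 lower on 1 side after 1.0 mg, 21 and 544 after 0.2 mg, and 2 and 22 after 0.1 mg. By at least 2-fold at every time point, 2 were higher and 6 lower after 0.2 mg. Probes at least 2-fold from vehicle numbered 1283 at 1 month and 11856 at 3 months after 0.2 mg and 2121 at 1 month after 1.0 mg. Subtracting a larger value from a wider array shifts all its probes down, by construction.

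Quantile normalization called 0 for the difference of the responses. It gave 35 higher and 8 lower on 1 side after 1.0 mg and 61 and 6 after 0.2 mg. By at least 2-fold at every time point, 10 were higher after 1.0 mg and 2 after 0.2 mg. The 2-fold counts became 833 at 1 week after 0.1 mg, 827, 1373 and 1251 at 1 week, 3 months and 6 months after 0.2 mg, and 898 and 1368 at 1 and 6 months after 1.0 mg. The lowest median at a time point left out was 0.208, against 0.453.

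Without the band of probes that shifted together, the 2-fold counts after 1.0 mg were 790 at 3 days and 1470 at 1 month, against 1384 and 3669.

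Leaving out each time point in turn, the calls ran from 0 to 1 for 0.2 mg and for the difference of the responses. On 1 side of vehicle, 76 to 167 were higher and 2 to 10 lower after 1.0 mg, 128 to 451 and 40 to 55 after 0.2 mg, and 11 to 90 and 3 to 42 after 0.1 mg. By at least 2-fold, 19 to 41 were higher and 2 to 5 lower after 0.2 mg, and 19 to 25 higher after 1.0 mg.

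Filters and floors on low values, the planned gene lists and the comparisons between vehicle samples were not run, as the table holds neither signal levels nor genes. Signal over background is not given in the sources used here.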

Other observations

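The 2-fold counts 3 months after 0.2 mg under each scaling, given last, were planned. All other tests in this part were chosen only after the result was seen. The 100 highest probes 6 months after 0.1 mg had a median of 2.07 there and 0.79 at 6 months after 0.2 mg, which shares the vehicle sample. In the 1.0 mg rats, with other vehicles, their medians were 0.37 at 3 days, -0.51 at 7 days, -1.27 at 30 days, 1.64 at 90 days and 0.36 at 180 days. Spread between rats that is independent from probe to probe is argued against by the value of 1.64 (random lists 0.09 to 0.24). Spread between groups of rats that many probes share is not, as the lists draw probes independently. A response to C60 of 1 sign at every dose and time point is argued against by the value of -1.27 (-0.07 to 0.25). A shift of whole arrays is argued against by a median of 1.62 at 90 days with each array centred on its median. The median of all probes had been 0.01 there. After quantile normalization the medians were 0.95 at 90 days and -0.89 at 30 days. A set of co-regulated genes that varied between groups of rats, in vehicle or treated lungs, is a candidate explanation and stays untested, since no gene names or single-rat values were at hand.

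Counted by a mean size of at least 2-fold, swings between time points involved nearly as many probes as the response of 1 sign. This did not hold for stricter counts. After 1.0 mg, exchanging vehicle and treated at 1 week and 1 month gave 0 probes at least 2-fold at every time point. The real arrangement gave 19. After 1.0 mg, 76 probes were above vehicle at 3 days and at 3 and 6 months and below it at 1 week and 1 month, with a mean size of at least 2-fold, and 36 of them were among the 100 highest 6 months after 0.1 mg.

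After 0.1 mg, exchanging vehicle and treated at 6 months gave 70 probes on 1 side at every time point with a mean of at least 2-fold, against 12 in the real arrangement. After 0.2 mg the real arrangement gave 199 and the highest of the other exchanges 77. Each low dose has 8 arrangements, too few for a share under 0.05. The exchanges used the values as deposited, while the counts on 1 side of vehicle depended on the scaling.

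The 0.2 mg sample at 3 months, which stood for 2 rats, had the widest differences from vehicle of the 13 treated samples (SD 0.75 over probes), and 19.6% of its probes lay within 0.25 of vehicle. Divided by what its numbers of rats give, its SD corresponded to 0.92 per rat, against at most 0.73 in the other samples. Relative to an SD predicted from the vehicle columns its ratio was 1.31, below 1.37 at 1 month after 1.0 mg and 1.34 at 6 months after 0.2 mg. The 3-month prediction rests on the vehicle column with the widest inferred spread per rat, 0.70. For 0.1 mg against the same vehicle sample the ratio was 0.69, so these ratios do not settle whether the 0.2 mg sample stood out. With each array centred on its median, 6913 of its probes were at least 2-fold from vehicle, and after quantile normalization 1373, against 6239 as deposited.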
